A study of Drosophila melanogaster with 24 samples.

How the data were processed

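Total RNA was sequenced from the abdominal carcass of adult female Drosophila melanogaster, that is, the fat body with the body wall after ovaries, gut and most of the Malpighian tubules had been dissected away. Each of 24 libraries came from 1 pool of 10 carcasses. There were 6 Control and 6 Selected replicate populations, and each of the 12 populations was raised on a standard and on a poor larval diet. The poor diet held 0.25 of the yeast, sugar and cornmeal concentration of the standard diet. Per the labels' protocols, each 40 ml of larval food received about 200 eggs. Adults of all groups were moved to standard food on day 1 and sampled at about 4 days, so diet refers to larval food only. The libraries were unpaired reads of 150 bp from 2 lanes. Whether reads were assigned by strand is not given in the sources used here, so reads of genes that overlap on opposite strands cannot be told apart.

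Per the submitters' processing notes, the authors quantified transcripts with kallisto 0.46.2 against build BDGP6, and limma and edgeR were also used. The deposited tables hold, per the file headers, estimated counts and TPM for each transcript and library. The estimated counts are fractional and not normalized. TPM was computed by the authors' quantification from estimated counts and effective length; effective length was the transcript length minus 100 for 99.94% of transcripts. A deposited table of the whole series holds log2 CPM for 8746 genes, which the authors call voom-normalised. For the 8558 genes shared with the gene sums made here, each column of that table correlated best with its own library (r of 0.982 or more, against 0.721 or less for any other library). Of its values, 98.8% lay within 0.05 of log2 CPM plus a constant per library.

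Of 30944 transcripts, 30811 were joined by identifier to the BDGP6.54 annotation, release 115. The 133 that were not joined carried 0.28% of counts and were left out. Estimated counts were summed over the transcripts of a gene, giving 14220 genes, of which 13895 were protein coding and 325 pseudogenes, and rounded to whole numbers. Near-identical copies share reads in such a quantification, so values of ribosomal RNA pseudogenes, of neighbouring Bomanin genes and of Amy-p are uncertain. Coordinates are those of BDGP6.54, counted from 1. Total estimated counts ranged from 29.4 to 31.5 M in 23 libraries, and the remaining library, Selected population S2 on standard diet, had 22.4 M. At these depths counting error weighs most on genes below about 1 CPM, and its share beside the spread between populations was not measured. No 2 libraries were duplicates of each other; their log2 CPM correlated at 0.9781 at most and 0.8408 at least.

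Groups were taken from the characteristics that the labels give for each library. The labels' titles contradict them: the title names the other diet in all 24 libraries, the other regime in 12, and the same population in 0. To see which field fits the libraries, 46 genes whose level fell into 2 separate classes (a gap of at least 1.5 on the log2 scale) were examined. The 2 libraries of a population had the same class in 488 of 552 cases by the characteristics and in 442 by the titles, and 1000 random pairings gave a median of 408 and at most 456. This check bears on the pairing into populations, and no value in the data tells which diet or regime name is right. All directions below therefore rest on the characteristics.

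Genes were tested with edgeR 4.0.16 (quasi-likelihood F test, TMM factors, R 4.3.3) after its filterByExpr filter over the 4 groups, which left 10184 genes. Benjamini-Hochberg adjusted p below 0.05 was called. For regime, the 2 libraries of a population were summed and 6 sums were compared with 6. For diet, all 24 libraries were fitted with population as a block, and the regime by diet interaction was added to that fit. The effects of regime within each diet and of diet within each regime were fitted on 12 libraries each. Standard errors were taken from the fold change and its F value. CPM in the text is TMM-normalised, with mean ± SD over populations. The pairing of a population's libraries comes from the labels; deviations of both libraries correlated at 0.22 on average (from -0.23 to 0.69), against -0.05 for other pairs of the same regime. The correlation of regime and diet fold changes across genes used equally weighted contrasts of log2 CPM. These share no error only where the spread is alike in the 4 groups. Its null was 100 reassignments of regime or flips of diet.

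The 45 gene lists cover metabolism, signalling, immunity, stress, reproduction, cuticle and markers of other tissues that a carcass could hold, and 1288 of their 1313 symbols were matched. Lists with at least 3 tested members (44 of 45) were tested with camera in limma 3.58.1 at a preset correlation of 0.01, with an estimated correlation, and with fry. The list of male reproductive genes had too few expressed members to test. An exact test of each list's mean log2 CPM (its score) was added after the data were examined: signs were flipped within the 12 populations for diet, and all splits of 12 populations into 6 and 6 were used for regime. All p-values are two-sided. Genes were named by a rule: among called genes of at least 2 log2 CPM the 8 largest rises and falls with a symbol other than a bare CG or CR number, the 2 largest each way with such a number, the 4 smallest p each way, up to 4 members per gene list, and the 5 smallest p of every other comparison. Where fewer than 5 genes were called, the 5 smallest p are given with values.

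The groups, gene lists, naming rule, tests and most alternatives were fixed before the data were examined. Alternatives were DESeq2 1.42.0, limma-voom with population as a random effect, limma on the deposited log2 table, counts rebuilt from TPM, other size factors, no low-count filter, thresholds of 0.1 and 0.01, marker scores as covariates, and leaving out each population. Added later were covariates for the share of ribosomal RNA pseudogene counts, for Malpighian tubule markers and for eggshell and midgut markers together, and fits without rRNA pseudogenes or with the genes of the authors' table only. The fits were tested on simulated counts for the same 10184 genes, 200 of them changed. Simulated genes varied independently of each other, without the variation shared across genes in the real libraries. Each simulated gene's dispersion was split in equal parts between population and library. The random-effect fit assumes 1 correlation for all genes, so these counts do not test that assumption. The rates given here need not hold for the real libraries. At a simulated 2-fold change edgeR recovered 68.7% for regime, 89.6% for diet and 59.7% for the interaction, with 7%, 3.4% and 3.3% false calls. DESeq2 made 22.1%, 15.9% and 21.4% false calls in the same simulations, and the random-effect fit recovered 70.1% for regime with 5.4% false.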

Results

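The data are 24 RNA-seq libraries from the abdominal carcass of mated Drosophila melanogaster females about 4 days old, each from a pool of 10 carcasses. Carcass here means fat body and body wall, with some hemolymph, oenocytes, neurons and fragments of tubule. The libraries form 4 groups of 6: Control or Selected populations, each raised as larvae on standard or on poor food and kept as adults on standard food. Total estimated counts ranged from 29.4 to 31.5 M, apart from 22.4 M in the Selected population S2 on standard diet. The labels' titles and characteristics disagree on the diet of every library; groups and all directions here follow the characteristics. What was measured is described below, and no conclusions are drawn. Fold changes are log2 values, Selected minus Control or poor minus standard, with ± giving the SE; CPM values are given as mean ± SD over populations.

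The largest differences between libraries lay in markers of tissues that the dissection aimed to remove. The first principal component held 32.1% of the variance, and its correlation with the score of 24 germline and oocyte genes was -0.97. The second held 18.6% and correlated at 0.92 with the score of 26 midgut digestive enzymes. Among these markers yl, the yolk receptor of the oocyte, ranged from 0.31 to 669 CPM, and the trypsin gene alphaTry from 3.54 to 5840 CPM. Germline scores averaged 4.01 in Selected and 2.75 in Control populations (6 and 6, exact p = 0.188). On poor diet they averaged 3.24 against 3.52 on standard diet (12 populations, 6 of them higher on poor, exact p = 0.729). Midgut scores averaged 1.67 in Selected and 1.73 in Control populations, and 1.33 on poor against 2.07 on standard diet (exact p = 0.366).

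**Figure D1:**
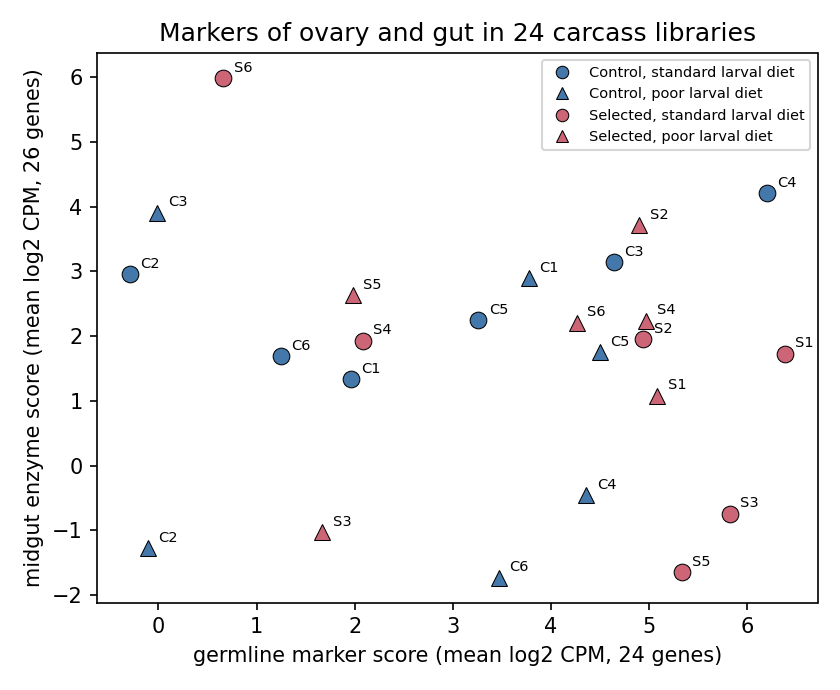
Scores of germline markers (24 genes) and midgut enzyme markers (26 genes) in each of the 24 libraries, as mean log2 CPM. Colour gives the regime, shape the larval diet, and labels the population.

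The 1st question was which genes differ between Selected and Control populations over the 2 larval diets combined. Of 10184 genes, 3 fell in Selected populations and 0 rose. The cytochrome P450 gene Cyp6a20 (FBgn0033980, 2R 14882118-14884046) fell by 3.93 ± 0.34, from 120 ± 57.9 CPM in 6 Control populations to 7.88 ± 2.75 CPM in 6 Selected ones (adjusted p = 7.63e-04). Every Selected population lay below every Control population for this gene. The other 2 were CG6912 (FBgn0038290, 3R 15135138-15137004; -0.86 ± 0.11, 18.3 against 32.6 CPM, adjusted p = 0.0215) and CG1299 (FBgn0035501, 3L 4148696-4152473; -0.85 ± 0.12, 54 against 96.1 CPM, adjusted p = 0.0484). For both, too, all 6 Selected populations lay below all 6 Control populations. Next by p, and not called, came CG30344 (-0.86 ± 0.13, adjusted p = 0.063) and CG9147 (-0.70 ± 0.12, adjusted p = 0.0913), again with 6 of 6 below. Genes picked for a small p of this test tend to be separated in this way, so the separation is no further support. Of all 10184 genes, 80 had regimes that did not overlap in the mean log2 CPM of a population's libraries. By chance 0.216% of genes would be so.

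**Figure D2:**
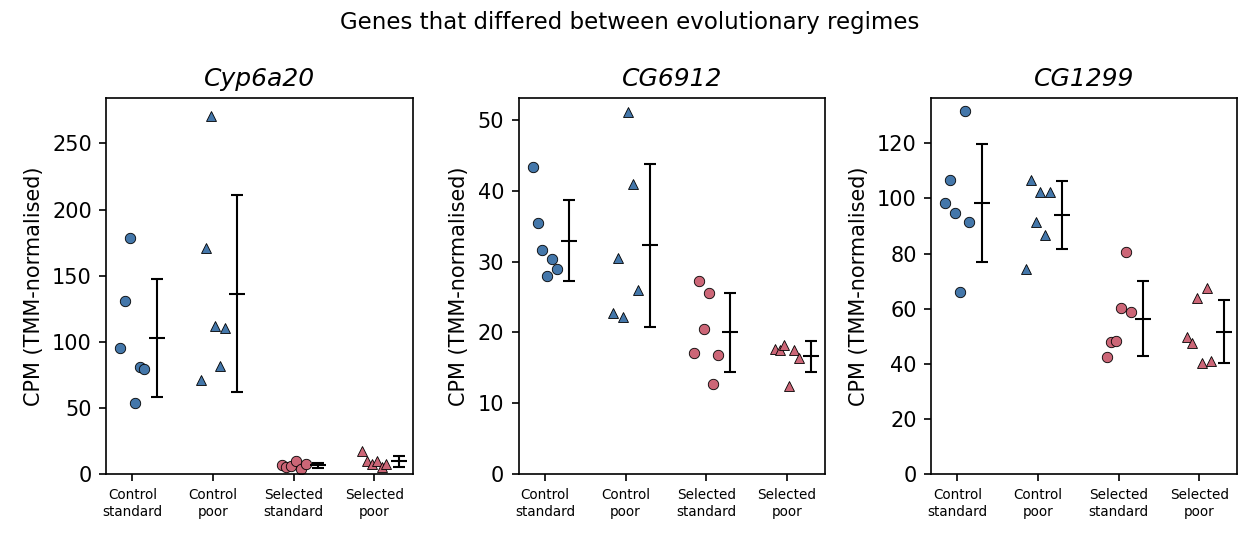
CPM of Cyp6a20, CG6912 and CG1299 in each library of the 4 groups. Bars give the mean and SD of 6 populations.

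Of 27 antimicrobial peptide genes in Selected populations 0 rose, 0 fell and 27 did not pass over all genes, and 9 were lower when adjusted over the list alone. In all, 25 of 27 had negative values, with a median of -0.76 (camera adjusted p = 2.27e-07; adjusted p = 0.815 with an estimated correlation). Among the 9 were AttB (-2.28 ± 0.63), BomT1 (-0.92) and BomS4 (-0.75 ± 0.19, 132 against 219 CPM). CecA1 (-2.31 ± 0.50, 6 Selected populations below all Control ones) was among them too, at only 0.106 against 0.521 CPM. The list score gave exact p = 0.0584 (adjusted p = 0.533). Of 30 immune recognition and signalling genes 0 were called over all genes and 2 over the list alone, the prophenoloxidases PPO1 (69.2 against 136 CPM) and PPO2 (84.8 against 166 CPM, 5 Selected populations below all Control ones), enzymes of melanization (list median -0.18, camera adjusted p = 6.69e-04; adjusted p = 0.91 with an estimated correlation).

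Beside these immune genes stand markers of hemocytes, the blood cells in the carcass. Of 16 members 0 passed over all genes and 5 over the list alone, 15 had negative values, and the median was -0.37 (camera adjusted p = 2.01e-05; adjusted p = 0.815 with an estimated correlation). NimC1, a phagocytic receptor, had -0.72 ± 0.15 (39.2 against 63.4 CPM, 5 Selected populations below all Control ones). NimC2 had -1.12 ± 0.24, crq -0.36 ± 0.10 and lz -0.87 ± 0.26 (at only 0.466 against 0.837 CPM). The hemocyte score was 5.51 ± 0.14 in Selected and 5.85 ± 0.25 in Control populations (exact p = 0.0173, adjusted p = 0.381). Among 13 iron and metal genes 0 passed over all genes and 4 over the list alone, namely Fer1HCH (-0.41 ± 0.13), Fer2LCH (-0.40 ± 0.12), Mvl (-0.21 ± 0.06) and MtnA (-0.84 ± 0.29), with 12 values negative and a median of -0.40 (camera adjusted p = 8.97e-04; adjusted p = 0.815 with an estimated correlation). Fer1HCH and Fer2LCH, the ferritin subunits, overlap on opposite strands, and Fer2LCH is also a member of the hemocyte list.

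Of 79 cytochrome P450 genes 1 fell over all genes (Cyp6a20) and 78 did not pass, with 4 lower over the list alone. Among the 4 were Cyp4ac1 (-1.72 ± 0.38, 7.39 against 23.5 CPM, 6 of 6 below) and Cyp9h1 (-1.27 ± 0.32). Cyp4d21 (-2.11 ± 0.48) was among them at only 0.0887 against 0.408 CPM. The list median was -0.13 (camera adjusted p = 0.00305; adjusted p = 0.91 with an estimated correlation). Of 25 UDP-glycosyltransferases 0 passed either way, and the median was -0.24 (camera adjusted p = 0.00407; adjusted p = 0.91 with an estimated correlation). Lipid transport (16 genes, 0 over all genes, 1 over the list alone, Karl at -0.56 ± 0.13; median -0.19) had camera adjusted p = 0.00757, and adjusted p = 0.91 with an estimated correlation. Lipolysis and fatty acid oxidation (22 genes, 0 either way, median -0.13) had camera adjusted p = 0.0438, and adjusted p = 0.924 with an estimated correlation. Glutathione S-transferases (29 genes, 0 either way, median -0.08, camera adjusted p = 0.624) and fatty acid and triglyceride synthesis (21 genes, 0 either way, median -0.11, camera adjusted p = 0.125) did not pass.

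Nuclear genes of oxidative phosphorylation had 67 of 69 values positive in Selected populations (0 passed either way, median 0.13, camera adjusted p = 1.34e-06; adjusted p = 0.91 with an estimated correlation). Mitochondrial ribosomal proteins had 60 of 73 positive (0 either way, median 0.09, camera adjusted p = 4.14e-05; adjusted p = 0.91 with an estimated correlation), and glycolysis and gluconeogenesis 16 of 19 (0 either way, median 0.11, camera adjusted p = 0.034; adjusted p = 0.91 with an estimated correlation). Genes of the TCA cycle (camera adjusted p = 0.123) and mitochondrially encoded mRNAs (camera adjusted p = 0.881) did not pass. All 24 germline and oocyte genes were positive (0 either way, median 0.92, camera adjusted p = 5.18e-08; adjusted p = 0.91 with an estimated correlation), as were all 21 cell cycle and replication genes (0 either way, median 0.70, camera adjusted p = 1.54e-05; adjusted p = 0.91 with an estimated correlation).

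In purine metabolism (20 genes, camera adjusted p = 0.613) 3 members passed over the list alone and 0 over all genes. Gart, an enzyme of purine synthesis, had 0.64 ± 0.15 (182 against 115 CPM, all 6 Selected populations above all Control ones), Adsl had 0.28 ± 0.08, and AMPdeam, the AMP deaminase, had -0.67 ± 0.14 (203 against 315 CPM). In the ecdysone list (19 genes, camera adjusted p = 0.394) 3 passed over the list alone and 0 over all genes: ImpE1 at 2.98 ± 0.62 (6.01 against 0.751 CPM, 6 of 6 above), Hr4 at -0.55 ± 0.13 and shd at -0.67 ± 0.20. Over the cuticle list alone 6 of 35 genes were higher and 1 lower, with 0 over all genes (camera adjusted p = 0.116). They included Cpr49Ae (0.96 ± 0.21, 1730 against 889 CPM), Cpr92F (1.23 ± 0.34), Cpr49Ah (1.30 ± 0.37) and Cpr47Ef (-1.37).

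The muscle genes TpnC73F (0.93 ± 0.20) and Act88F (1.20 ± 0.34) were higher and TpnC47D (-0.49) lower over the muscle list alone, of 26 genes and 0 over all genes (camera adjusted p = 0.575). Eggshell genes gave 2 higher and 2 lower of 14 over the list alone and 0 over all genes (median 1.58, camera adjusted p = 0.167). Cp15 had -2.87 (0.375 against 2.72 CPM), Cp18 -2.40 (0.302 against 1.56 CPM) and Fcp3C 2.98. Cp36 averaged 40.1 ± 96.6 against 0.107 ± 0.0946 CPM. Single populations carried both high values, with Cp36 at 237 CPM in S1 (next 1.73) and Fcp3C at 6.76 CPM in S5 (next 0.474). Single members passed over their list alone, and 0 over all genes, in sugar digestion (Amy-p, -3.57 ± 0.98, with 94.6 CPM in C4, 31.3 in the next Control population and 1 Selected population below all Control ones), Malpighian tubule markers (Mco1, -0.55 ± 0.14), odorant binding proteins (Obp57b, -0.42 ± 0.10) and the autophagy and starvation list (Atg9, -0.30 ± 0.08). In the sex-biased and circadian lists Cyp4d21 was again the single such member. Midgut enzymes had a median of 0.35 and a mean of 0.53, but a camera direction of down (adjusted p = 0.0997). The remaining lists passed in 0 members either way and had camera adjusted p of 0.054 or more.

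The regime test compared 6 with 6 population sums in edgeR. Unadjusted p was below 0.05 for 1087 genes, where 509 would be so on average by chance. Some random splits of the populations gave more than 1087, for example 2709, so this excess alone does not show a regime effect. By other fits 221 genes were called with DESeq2 and 125 with population as a random effect in limma, and 0 when populations of like number were blocked, where Cyp6a20 had -3.89 (adjusted p = 0.0815). Cyp6a20 was called with any single population left out, while CG6912 was lost without C1, C2, C5, S1, S3 or S6 (adjusted p from 0.0549 for CG6912 without C2 to 0.112 without S1). CG1299 was lost without any population but C4 and S5 (from 0.054 without C3 to 0.16 without S3). Counts were 1 without C1, C5, S1 or S3, 5 without S4 and 36 without C4.

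The 2nd question was which genes of the adult carcass differ with larval diet across all 12 populations. On poor larval diet 88 genes rose and 27 fell, and all 115 had the same sign in the Control and in the Selected populations. The 115 were called on both regimes jointly, which favours genes of like sign, so this agreement is no separate test. Genes of the yolk, made in fat body and follicle cells and taken up by oocytes, gave the largest falls in abundant transcripts. Yp1 (FBgn0004045, X 10053811-10055498) fell by 1.32 ± 0.28, from 35100 ± 13700 to 16400 ± 10500 CPM, and was lower on poor diet in 12 of 12 populations (adjusted p = 0.0428). Cht6, a chitinase (FBgn0263132, X 10016845-10050803), rose by 0.97 ± 0.13, from 34.9 to 70.1 CPM, in 12 of 12 populations (adjusted p = 0.0107). The insulin receptor InR (FBgn0283499, 3R 21570248-21619321) rose by 0.57 ± 0.10, from 49.6 ± 8.53 to 74.5 ± 16.5 CPM, in 12 of 12 (adjusted p = 0.0232).

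**Figure D3:**
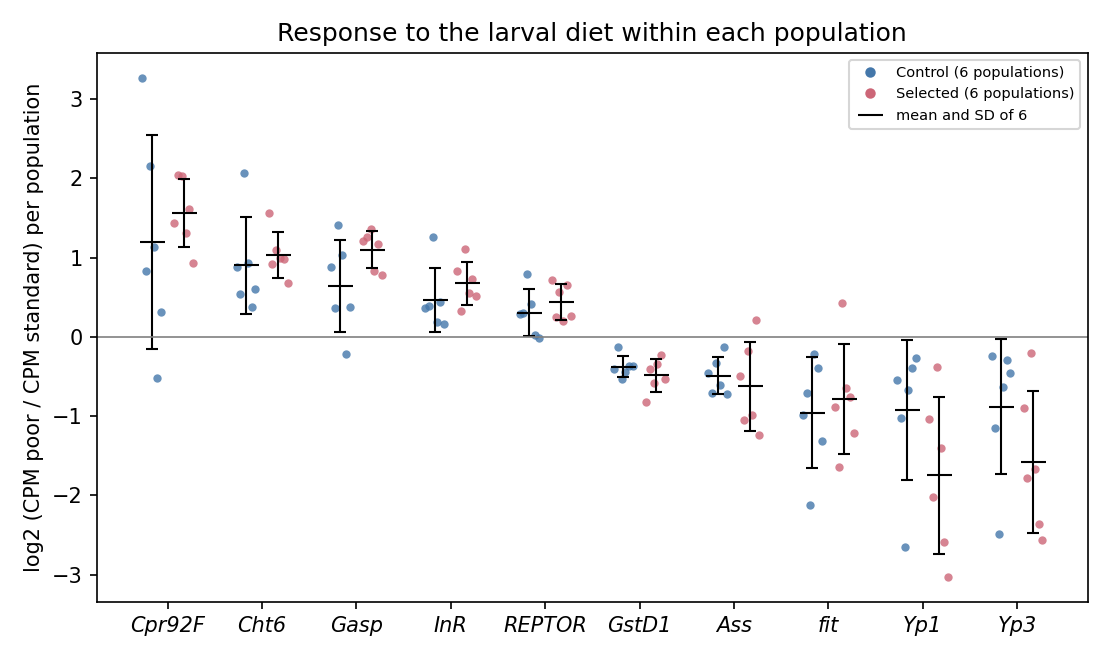
Log2 ratio of CPM on poor to CPM on standard diet for 10 genes, with 1 point per population. Bars give the mean and SD of the 6 Control and of the 6 Selected populations.

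Of 35 cuticle genes 8 rose, 0 fell and 27 did not pass over all genes, and 14 were higher over the list alone. Negative values numbered 13 of the 35 (median 0.15, camera adjusted p = 3.95e-04; adjusted p = 0.7 with an estimated correlation). Among them Cpr92F (FBgn0038819, 3R 20669571-20672821) rose by 1.38 ± 0.26, from 137 ± 73.2 to 343 ± 204 CPM (11 of 12 populations, adjusted p = 0.0312). Cpr100A (0.97 ± 0.17, 11 of 12, adjusted p = 0.0232), Cpr97Eb (0.85 ± 0.15, 11 of 12, adjusted p = 0.0232) and Cpr47Ea (0.94 ± 0.17, 10 of 12, adjusted p = 0.0281) rose too. Higher over the list alone were also Cpr49Ae (0.64), Cpr64Ac (0.96), Cpr62Bb (0.37) and Cpr67B (0.29). The list score was higher on poor diet in 8 of 12 populations (exact p = 0.0474, adjusted p = 0.233).

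Also in that list, Cpr49Ah (FBgn0033731, 2R 12413962-12415170) rose by 1.34 ± 0.28 (11 of 12, adjusted p = 0.0406). Outside it the adult cuticle protein Acp1 (FBgn0014454, 2L 7740562-7741537) rose by 1.14 ± 0.25 (11 of 12, adjusted p = 0.0444). Gasp, a chitin-binding protein (FBgn0026077, 3R 6088799-6100887), rose by 0.88 ± 0.13, from 94.2 to 173 CPM (11 of 12, adjusted p = 0.0195). The pigmentation gene y (FBgn0004034, X 356509-361245; 1.17 ± 0.22, 12 of 12, adjusted p = 0.0285) and f, whose product bundles actin in bristles (FBgn0262111, X 17232942-17280964; 1.11 ± 0.15, 12 of 12, adjusted p = 0.0107), rose as well. Further rises were CG15080 (1.21 ± 0.18, 12 of 12, adjusted p = 0.0195), MFS9 (1.21 ± 0.21, 11 of 12, adjusted p = 0.0238), b6 (0.99 ± 0.18, 11 of 12, adjusted p = 0.0281), CG13947 (1.88 ± 0.38, 10 of 12, adjusted p = 0.0381) and CG8736 (1.76 ± 0.31, 10 of 12, adjusted p = 0.027). The pseudogene 28SrRNA-Psi:CR45862 rose by 1.01 ± 0.18 in 12 of 12 (adjusted p = 0.0256). The share of rRNA pseudogene counts in a library was 3.29 ± 0.956% on poor and 2.28 ± 2.26% on standard diet, higher on poor in 11 of 12 populations (exact p = 0.19). The exception was S2, at 9.3% on standard diet, where the other 11 populations had 2.59% or less. The exact test used raw percentages, so the large opposite difference of S2 (3.13% on poor diet) weighed heavily in its p. That p therefore does not show that the share was unrelated to diet.

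All 3 yolk protein genes fell, over all genes and over the list alone. Beside Yp1 these were Yp2 (FBgn0005391, X 10050951-10052636; -1.50 ± 0.33, 16400 to 6980 CPM, adjusted p = 0.048) and Yp3 (FBgn0004047, X 13759546-13761547; -1.22 ± 0.25, 8630 to 4390 CPM, adjusted p = 0.0389), each lower in 12 of 12 populations (camera adjusted p = 3.95e-04; adjusted p = 0.542 with an estimated correlation). The yolk score fell by 1.37 (SD 1.02) in 12 of 12 populations (exact p = 0.000488, adjusted p = 0.0107). Of 12 adult fat body genes 4 fell, 0 rose and 8 did not pass, with 5 lower and 1 higher over the list alone (median -0.71, camera adjusted p = 0.0218; adjusted p = 0.7 with an estimated correlation). The 4 were the yolk genes and fit, a peptide gene of the female fat body (FBgn0038914, 3R 21883924-21884454; -0.87 ± 0.19, lower in 11 of 12, adjusted p = 0.0439); apolpp had -0.78 ± 0.23 and Obp99b 0.66. These yolk and fat body genes stand beside eggshell genes with 12 of 14 values negative (0 passed either way, median -0.69, camera adjusted p = 0.0218; adjusted p = 0.7 with an estimated correlation) and germline genes with 16 of 24 negative (0 either way, median -0.14, camera adjusted p = 0.0647).

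Glutathione S-transferases were lower on poor diet. Of 29 members 1 fell, both over all genes and over the list alone, and 25 had negative values (median -0.14, camera adjusted p = 0.00182; adjusted p = 0.217 with an estimated correlation). GstD1 (FBgn0001149, 3R 12367817-12369268) fell by 0.43 ± 0.05, from 225 ± 48.6 to 166 ± 30.8 CPM, in 12 of 12 populations (adjusted p = 0.0107), and the list score fell by 0.23 (SD 0.11) in 12 of 12 (exact p = 0.000488, adjusted p = 0.0107). Heat shock proteins had 1 of 14 members falling, over all genes and over the list alone, Hsp68 (-0.50 ± 0.11, lower in 11 of 12, adjusted p = 0.0481), and a median of -0.21 (camera adjusted p = 0.0362; adjusted p = 0.542 with an estimated correlation). Other falls were fiz, a predicted ecdysone oxidase (FBgn0030594, X 14906334-14909708; -1.38 ± 0.22, 12 of 12, adjusted p = 0.0195), and Papss, which makes the sulfate donor PAPS (FBgn0020389, 3L 19845293-19860925; -0.51 ± 0.08, 12 of 12, adjusted p = 0.0195). CG31373 (-0.82 ± 0.12, adjusted p = 0.0195) and CG4259 (-0.78 ± 0.14, adjusted p = 0.0281) fell, also with 12 of 12 lower.

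In the insulin and TOR list (27 genes) 2 rose, 0 fell and 25 did not pass over all genes, and 4 were higher and 1 lower over the list alone (median 0.08, camera adjusted p = 0.00235; adjusted p = 0.7 with an estimated correlation). They were InR, Ilp6 (0.46 ± 0.12), Pdk1 (0.23), the amino acid transporter gene slif (-0.74 ± 0.19) and REPTOR (FBgn0039209, 3R 24557368-24582864), a transcription factor restrained by TOR. REPTOR rose by 0.37 ± 0.07 from 128 to 164 CPM (11 of 12, adjusted p = 0.0375). The autophagy and starvation list (17 genes) had 1 rise over all genes, InR, and 3 over the list alone, with Ilp6 and Atg17 (0.24) the others (median 0.11, camera adjusted p = 0.00122; adjusted p = 0.7 with an estimated correlation). Of 10 glycogen and trehalose genes 0 passed over all genes and 3 over the list alone, Gyg (0.27), Glyp (0.32) and AGBE (0.35), with a median of 0.17 (camera adjusted p = 0.00535; adjusted p = 0.7 with an estimated correlation).

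In amino acid metabolism 1 of 37 genes fell over all genes and 3 over the list alone (median 0.05, mean -0.01, camera adjusted p = 0.85). Ass, the argininosuccinate synthetase (FBgn0026565, 3R 6642262-6644434), fell by 0.56 ± 0.11, from 34.8 to 23 CPM (lower in 11 of 12, adjusted p = 0.0381), beside Argl (-0.59) and Shmt (-0.28). Purine metabolism had 0 of 20 members passing either way (camera adjusted p = 0.779), while its score was lower by 0.18 in 11 of 12 populations (exact p = 0.00244, adjusted p = 0.0358); without S2 the adjusted p was 0.0716. The adult fat body score, lower by 0.53 in 9 of 12 populations (exact p = 0.00391, adjusted p = 0.043), likewise had 0.0859 without S2.

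Of 27 antimicrobial peptide genes 1 rose over all genes on poor diet, BomS3 (FBgn0040736; 0.42 ± 0.09, 485 to 631 CPM, 10 of 12, adjusted p = 0.0439), and 2 over the list alone, with BomS2 (0.62) the other (21 values positive, median 0.21, camera adjusted p = 0.00174; adjusted p = 0.725 with an estimated correlation). Of 30 immune recognition genes 0 passed over all genes and 2 over the list alone, PGRP-LF (0.42) and Rel (0.30), with a median of 0.12 (camera adjusted p = 0.00385; adjusted p = 0.7 with an estimated correlation). Beside them 14 of 16 hemocyte markers were positive (0 passed either way, median 0.13, camera adjusted p = 0.00182; adjusted p = 0.7 with an estimated correlation).

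On poor diet mitochondrial ribosomal proteins had 71 of 73 values negative (0 passed either way, median -0.14, camera adjusted p = 1.75e-09; adjusted p = 0.7 with an estimated correlation). Oxidative phosphorylation had 66 of 69 negative (0 either way, median -0.13, camera adjusted p = 2.99e-06; adjusted p = 0.735 with an estimated correlation), and cytoplasmic ribosomal proteins 79 of 86 (0 either way, median -0.08, camera adjusted p = 0.00488; adjusted p = 0.892 with an estimated correlation). Mitochondrially encoded mRNAs had 8 of 13 positive (0 either way, median 0.10, camera adjusted p = 0.365), and the TCA cycle list did not pass (camera adjusted p = 0.426). All 21 cell cycle and replication genes were negative (0 either way, median -0.45, camera adjusted p = 1.65e-04; adjusted p = 0.725 with an estimated correlation). Neuron markers were all positive (18 genes, 0 over all genes, 1 over the list alone, elav at 0.42; median 0.34, camera adjusted p = 1.16e-04; adjusted p = 0.7 with an estimated correlation). Of 26 muscle genes 21 were positive (0 over all genes, 1 over the list alone, TpnC73F at 0.31; median 0.12, camera adjusted p = 0.00235; adjusted p = 0.735 with an estimated correlation).

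Lists without a camera call also held called genes. Among 11 sex-biased fat body genes fru rose (0.35 ± 0.07, 12 of 12, adjusted p = 0.0299) and 4 fell (camera adjusted p = 0.346). The 4 were Yp1, Yp2, Yp3 and fit, the same genes as in the adult fat body list above. Over the list alone 2 were higher and 5 lower, Obp99a at -1.57 among them. Of 79 P450 genes 1 rose, Cyp4ac3 (0.56 ± 0.12, 11 of 12, adjusted p = 0.0439), with 1 higher and 1 lower (Cyp6w1, -0.66) over the list alone (camera adjusted p = 0.647). Of 17 odorant binding proteins 1 rose, Obp83g (FBgn0046875; 1.06 ± 0.18, 11 of 12, adjusted p = 0.0232), with 2 higher and 2 lower over the list alone, Obp56d (-0.49) among them (camera adjusted p = 0.938). Over the list alone, and 0 over all genes, passed gce (0.31) and Jheh1 (-0.31) in the juvenile hormone list, Eip74EF (0.36) and Hr38 (0.50) in the ecdysone list, and Arc42 (-0.24) in lipolysis. Midgut enzymes (20 of 26 negative, median -0.98, camera adjusted p = 0.117) and Malpighian tubule markers (12 of 15 negative, median -0.25, camera adjusted p = 0.104) passed in 0 members either way, as did all lists not named here, with camera adjusted p of 0.0585 or more.

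The diet test used edgeR on 24 libraries with population as a block, and 1793 genes had unadjusted p below 0.05. Some random flips of diet within populations gave more than 1793, for example 3284, so this number alone does not show a diet effect. DESeq2 called 548 genes and the random-effect fit 164. With Cht6, f and GstD1 called each time, counts fell to 3 without S1, 4 without S5, 22 without S3, 23 without S2, 38 without S4, 40 without C3, 43 without S6, 47 without C4 and 49 without C1 or C2, and Yp1, for example, had adjusted p = 0.0865 without S1. Counts were 0 with the share of rRNA pseudogene counts or the Malpighian tubule score as a covariate. All 115 genes kept their sign and unadjusted p below 0.05 in both (medians from 0.68 to 0.64 or 0.65 for rises and from -0.50 to -0.49 or -0.48 for falls). With no block 21 genes were called, while 178 were called with eggshell and midgut scores as covariates.

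A 3rd question was whether the effect of larval diet differs between the regimes. No gene was called for the interaction by edgeR: 155 of 10184 had unadjusted p below 0.05, and DESeq2 called 1 gene and the random-effect fit 0. The smallest p belonged to Pfas, an enzyme of purine synthesis (0.43 ± 0.09, adjusted p = 1 in edgeR), at 137 and 137 CPM on standard and poor diet in Control and 152 and 206 CPM in Selected populations. Next were sing (1.52 ± 0.33), thw (1.49 ± 0.33) and frac (1.02 ± 0.26), with adjusted p = 1, and CG12506, which stayed at 1.14 CPM or below in every group mean. Of the 88 genes that rose with poor diet 10 had unadjusted p below 0.05 for the interaction, and of the 27 that fell 2 had.

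For the interaction 19 lists had camera calls and 0 passed with an estimated correlation, with fry or with exact list scores. Ribosomal proteins ranked first, with 83 of 86 values positive (0 genes over all genes, median 0.16, camera adjusted p = 1.14e-18; adjusted p = 0.681 with an estimated correlation). Glycogen and trehalose genes were all positive (10 genes, 0 over all genes, median 0.22, camera adjusted p = 8.50e-07; adjusted p = 0.505 with an estimated correlation), and 13 of 14 eggshell genes negative (0 over all genes, median -1.06, camera adjusted p = 1.15e-07; adjusted p = 0.366 with an estimated correlation). The Malpighian tubule score changed by -0.04 with poor diet in Control and by -1.31 in Selected populations (exact p = 0.0541, adjusted p = 0.816). For the yolk score these values were -0.94 ± 0.91 and -1.79 ± 1.01 (mean ± SD, exact p = 0.152). The interaction term joined the fit with population as a block. In simulated counts, where genes varied independently of each other, 59.7% of 2-fold interactions were recovered. The share for the real libraries, whose genes vary together, was not measured.

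What regime does within each larval diet was tested on 12 libraries each in edgeR. On standard diet only Cyp6a20 was called, which fell by 4.01 ± 0.33 in Selected populations (103 ± 44.7 to 6.34 ± 2.06 CPM, adjusted p = 4.11e-04). Next by p were CG11893 (-2.80 ± 0.46, adjusted p = 0.233), Prestin (-0.53 ± 0.09, adjusted p = 0.233), mtt (2.21 ± 0.40, adjusted p = 0.34) and Hao (1.46 ± 0.28, adjusted p = 0.34), and 650 genes had unadjusted p below 0.05. On poor diet 6 genes fell and 0 rose. These included Cyp6a20 (-3.85 ± 0.40, adjusted p = 0.00432), Inos, the inositol phosphate synthase (FBgn0025885, 2R 7454922-7458874; -0.53 ± 0.08, 147 against 212 CPM), CG9147 (-0.68 ± 0.10), CG15202 (-0.88 ± 0.13) and CG43175 (-2.62 ± 0.40), the last 4 with adjusted p = 0.0471. The gene ranking 6th, named after its value was seen, was AMPdeam (-0.59 ± 0.09, adjusted p = 0.0471). Of the calls on the 2 diets 1 was shared, Cyp6a20. Inos was lost without any 1 population except C3 and S5 (for Inos, adjusted p = 0.192 without S2), as were most of the others. The count ranged from 1 without C1, C5, C6, S1, S2, S3 or S6 to 12 without C3, with 3 without S5 and 2 without C2, C4 or S4.

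Diet within each regime was fitted on 6 pairs of libraries. In Control populations 0 genes were called by edgeR (393 with unadjusted p below 0.05, smallest adjusted p = 0.92), and DESeq2 called 15. The smallest p belonged to Diedel (-1.53 ± 0.28), Ilp8 (-3.71 ± 0.71), Ass (-0.49 ± 0.10), GstD1 (-0.37 ± 0.07) and Muc12Ea (3.5 to 0.00596 CPM), all with adjusted p = 0.92. In Selected populations 43 genes rose and 21 fell, of which 33 were among the 115 of the joint test, and 61 of the 64 had the same sign in Control populations. The difference between these counts is not a test; the interaction above is.

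In Selected populations salt (FBgn0039872, 3R 31751825-31754705) fell by 3.61 ± 0.20, from 29.7 ± 12.7 to 2.36 ± 0.969 CPM (adjusted p = 0.00261), with 17 and 15.1 CPM in Control. Rises included CG13947 (2.68 ± 0.20, 129 to 787 CPM, adjusted p = 0.0118), MFS9 (1.41 ± 0.11, adjusted p = 0.0118), Gasp (1.12 ± 0.09, 101 to 215 CPM, adjusted p = 0.0134) and CG8927 (2.11 ± 0.20, adjusted p = 0.0213). Malpighian tubule scores stand beside them, at 3.51 ± 0.49 on standard and 2.20 ± 0.51 on poor diet in Selected populations and 2.58 and 2.54 in Control. With edgeR on 12 libraries, salt was called with any population left out, while the count was 1 without S1, 2 without S2 or S3, 15 without S6, and 30 without S4 or S5. It was 0 with the Malpighian tubule score as a covariate and 2 with eggshell and midgut scores.

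A last question was whether genes that differ between regimes also respond to diet, and in which direction. Across 10184 genes the fold changes of regime and of diet correlated at -0.16, with p = 0.68 by 100 permutations of regime among populations and p = 0.70 by 100 random flips of diet. Among the 118 genes called in either test r was 0.46 (permutation p = 0.37 and 0.32). By edgeR 0 genes were called in both tests. With the random-effect fit 12 genes were higher both in Selected populations and on poor diet, where 0.627 would fall together if the 48 and 133 such calls were independent; 0 were shared in any other direction. These 12 were Acp65Aa, b6, Cad86C, CG10936, CG15080, CG3777, CG8927, CG9095, CG9427, Cht6, Cpr49Ae and Cpr49Ah. With eggshell and midgut scores regressed out first, r was 0.19 (permutation p = 0.10 and 0.08).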

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

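Of 144 groups of 6 values examined, 14 held a value far from the others, where chance flags about 1 in 20 groups of normally distributed values. Many groups were CPM on the raw scale, which need not be so distributed, so the 14 are not read as an excess. The flagged values are given first, and 3 patterns are then weighed. The tests of ovary and gut markers, of yolk genes and of list splits were chosen after the result was seen. So were the splits for diet in all populations, for regime over both diets in edgeR, and for the interaction. The others were written down before their results were known. Among those were the splits for the random-effect fit, for regime within each diet and for diet within each regime.

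Selected population S2 on standard diet had 22.4 M counts (next value of its group 30.3) and a share of rRNA pseudogene counts of 9.3% (next 2.59%). In S3 on poor diet 9582 genes had at least 10 counts (next 9792). Eggshell scores were 2.85 in C5 on poor diet (next -1.21) and 2.07 in C4 on standard diet (next -0.70). As means of a population's 2 libraries, CG1299 was 74 CPM in S5 (next 55.9), CecA1 1.2 in C2 (next 0.444), AttB 3.53 in S6 (next 1.21), Amy-p 94.6 in C4 (next 31.3) and Cyp9h1 32.8 in C1 (next 19.4). Cp36 was 0.292 CPM in C2 (next 0.113) and 237 in S1 (next 1.73), Fcp3C 6.76 in S5 (next 0.474), and Mco1 3.43 in S1 (next 5.71).

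For the 115 genes that differed between larval diets, chance was weighed by flipping diet within populations. Only 1 of 100 splits, the real one, called as many, and the highest other called 0. Chance is thus unlikely for this count, but not excluded. By unadjusted p below 0.05 in edgeR the real labels gave 1793 genes, and some flips gave more, for example 3284. RNA from ovary or gut left in the carcass could have carried the difference. With eggshell and midgut scores as covariates 89 of the 115 calls were kept. For those 89 genes this argues against RNA that follows these scores as the whole cause. The germline score correlated more strongly with the first principal component (-0.97, against -0.82 for eggshell) and was not used as a covariate. Ovary RNA that the eggshell score does not follow was therefore not tested. In Selected populations alone the same covariates took the diet calls from 64 to 2. RNA quality, read from the share of rRNA pseudogene counts, cannot be told apart from diet: that share correlated with the score of the called genes at a rho of 0.02 among libraries on standard diet and of 0.76 among those on poor diet (n = 12 each, permutation p = 0.956 and 0.00586, adjusted p = 0.0117 for the second). With that share as a covariate 0 genes were called, while the median of the genes that rose went from 0.68 to 0.64 with its SE from 0.13 to 0.17. With the Malpighian tubule score as a covariate the median was 0.65 and the smallest adjusted p 0.0614 in edgeR.

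Lower yolk protein genes on poor diet might reflect less follicle cell RNA from ovary pieces in those carcasses. In the 6 populations whose germline score was higher on poor diet, the yolk score was still lower in all 6, by -1.16 on average (SD 1.09), against -1.57 (SD 0.99) in the other 6. Germline genes are not markers of follicle cells, so eggshell genes, which are, were also used, after the result was seen. The yolk score was lower in all 5 populations with a higher eggshell score on poor diet (mean -0.92, SD 0.80) and in all 7 others (mean -1.68, SD 1.09); in the 4 with both scores higher the mean was -0.65 (SD 0.61). These values argue against ovary pieces as the whole cause, and a part of the difference might still come from them, given the smaller mean of -0.92.

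The count of genes that differed between regimes depended on the model, with 3 genes by edgeR on population sums, 125 with population as a random effect and 221 by DESeq2. Chance was weighed by 100 splits of the populations, the real one included. In edgeR 3 of them called 3 or more genes, and the highest other called 42. Chance is thus unlikely but not excluded, and a split calling several times the real count points to structure of the populations. For the random-effect fit 2 of 60 splits called 125 or more and the highest other called 177, so chance is again unlikely, not excluded. A single correlation between the 2 libraries of a population, 0.27 for all genes, may be too low for the genes called, whose median was 0.54 (quartiles 0.34 and 0.71), but these genes were chosen by the regime test itself, and the explanation stays open.

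Other splits gave further values. For the interaction (real 0) 100 of 100 splits called as many, as any split must, so chance cannot be excluded and was not tested by this count; the highest other called 3227, which points to structure of the samples. Regime on standard diet was matched by 3 of 100 splits (real 1, highest other 1604). Regime on poor diet was matched by 3 of 100 (real 6, highest other 185). Chance is unlikely for both but not excluded. Single splits called many times the real count, which points to structure of the samples. Diet in Control populations (real 0, highest other 1) was matched by 32 of 32 splits, again as any split must, so chance cannot be excluded and was not tested by this count. Diet in Selected populations was matched by 2 of 32 (real 64, highest other 1053), so chance cannot be excluded and the samples hold structure beyond these groups. Camera at the preset correlation called as many lists in 53 of 100 regime splits (real 13, highest other 27), 35 of 100 diet splits (real 18, highest other 28) and 34 of 100 interaction splits (real 19, highest other 26), so chance cannot be excluded for those list counts.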

How the results depend on the processing

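The counts depended on the processing more than the directions did. Of 3075 values for named genes under other settings, 2490 kept their side of the threshold and their direction, 458 kept the direction and lost the call, 127 kept it and gained a call, and 0 turned. Groups from the titles, which turn the diet by construction, were run for counts of genes and are not among these values. For gene lists 537 of 750 were the same, 213 lost the call and 0 turned. The covariates for the rRNA share, for Malpighian tubule markers and for eggshell with midgut markers were chosen after the data were examined. So were the fits without rRNA pseudogenes or with the authors' genes, and the exact list scores. The covariate for eggshell markers alone was planned. Genes called for regime (3) numbered 13 at a threshold of 0.1 and 1 at 0.01, 221 with DESeq2, 125 in limma with population as a random effect, 115 in limma on the authors' table, 1 with eggshell and midgut covariates, 1 with the rRNA share as a covariate, 0 with groups from the titles and 0 with a replicate block. For diet (115) there were 288 at 0.1 and 0 at 0.01, 548 with DESeq2, 183 in limma on the authors' table, 178 with eggshell and midgut covariates, 0 with the rRNA share and 0 with the Malpighian tubule covariate, 0 with groups from the titles and 21 with no replicate block. DESeq2 called 1 gene for the interaction (0) and 15 for diet in Control populations (0). Regime on standard diet (1) had 51 with DESeq2, 0 with groups from the titles and 0 with a replicate block. Regime on poor diet (6) had 11 at 0.1, 1 at 0.01, 210 with DESeq2, 1 with RLE factors, 1 with no low-count filter, 1 with eggshell and midgut covariates, 2 with the rRNA share, 1 with the genes of the authors' table, 0 with groups from the titles and 0 with a replicate block. Diet in Selected populations (64) had 120 at 0.1, 1 at 0.01, 395 with DESeq2, 2 with eggshell and midgut covariates, 1 with the rRNA share, 0 with the Malpighian tubule covariate and 0 with groups from the titles. Lists called by camera (13 for regime, 18 for diet and 19 for the interaction) numbered 0, 0 and 0 with an estimated correlation, 0, 3 and 0 with fry and 0, 4 and 0 with exact list scores. Correlation of regime and diet fold changes (-0.16) was 0.46 among called genes, 0.23 for diet in Control against regime on standard diet, where shared Control libraries alone gave a median of 0.36, -0.29 for diet in Control against regime on poor diet, where they gave -0.33, and 0.19 with eggshell and midgut scores regressed out. Leaving out 1 population at a time gave 1 to 36 genes for regime, 3 to 139 for diet, 0 to 0 for the interaction, 1 to 2 and 1 to 12 for regime on standard and poor diet, and 0 to 0 and 1 to 30 for diet in Control and Selected populations. For lists it gave 13 to 17, 17 to 22 and 15 to 23, and for the correlation -0.28 to -0.06. All other settings kept the counts within 1.5 times those reported. The cause was not tested. With 22.4 M counts or more per library, counting error weighs most on genes below about 1 CPM. How much the spread between populations limited the other genes was not measured.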

Other observations

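Beyond the named genes, chosen after their values were seen, further genes of chitin and cuticle rose on poor larval diet in the adult carcass (edgeR, 12 populations). The chitin synthase kkv rose by 0.93 ± 0.21 (adjusted p = 0.0487), and the chitin deacetylases serp by 0.58 ± 0.13 (adjusted p = 0.0444), verm by 0.69 ± 0.12 (adjusted p = 0.0232) and Cda5 by 0.77 ± 0.12 (adjusted p = 0.0202). The chitinase Cht7 rose by 0.63 ± 0.13 (adjusted p = 0.0381), the cuticle proteins Acp65Aa by 0.90 ± 0.18 (adjusted p = 0.0381) and Cpr97Ea by 0.92 (adjusted p = 0.0375), and Vajk2 and Vajk3 by 0.71 each (adjusted p = 0.0207 and 0.0195). Other rises were Myc (0.39 ± 0.09, adjusted p = 0.0487) and Abd-B (0.50, adjusted p = 0.0308). Falls included the glycerol kinase Gk2 (-0.45, adjusted p = 0.0358) and the aldehyde dehydrogenase Aldh7A1 (-0.48, adjusted p = 0.0238). No list of chitin enzymes was fixed before the data were examined, so this group has no test of its own.

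Some genes were high or low in single populations on both larval diets, in either regime, and are given as CPM on poor and standard diet, chosen after their values were seen. The P450 gene Cyp6g2 was high in S5 (62.4 and 40.9) and S6 (58.9 and 53.8) against 2.04 to 14 elsewhere, while Cyp6a17 was low in the same populations (2.61 and 1.97 in S5, 1.95 and 2.74 in S6) and at least 11.3 elsewhere. The lysozyme gene LysD was low in S2 (6.31 and 11.5) and S4 (9.05 and 12.1), Sema1a was high in S4 (74.3 and 62.5), and CngA was high in C1 (75.8 and 106, others 9.55 or less). In C5, p24-2 had 0 on both diets, and Obp99a had 0.147 and 0. In Selected populations on poor diet the transporter genes Oatp58Db (-3.48, adjusted p = 0.0286), Oatp58Dc (-2.96, adjusted p = 0.0405) and Smvt (-3.50, adjusted p = 0.0387 in edgeR) fell, beside the lower Malpighian tubule score of that group. Oatp58Db and Oatp58Dc are members of the Malpighian tubule list, so their fall is part of that score and not separate from it.

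Hypotheses were tested as follows, with predictions written down before their results were known. If the evolved change went the same way as the response to diet, called diet genes could share the sign of the regime difference more often than under reassigned regimes. By equally weighted contrasts 85 of the 115 did, but 25 of 100 reassignments gave as many and the highest other gave 98, so this was not borne out. With the random-effect fit 12 genes were called for both and at most 4 in 59 other reassignments. Most of those called 0 genes for regime, so few could be shared, and this count cannot decide. If differences between regimes were linked along chromosomes, the 100 genes with the smallest regime p could lie close together: 31 had a neighbour among them within 100 kb, 26 of 100 splits gave as many (median of the others 26, highest 46), while 1000 random sets of genes had a median of 19 and at most 36. Any split of populations may carry linked differences, so the splits are no test without linkage, and the 31 leave this open.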
